A study of Mus musculus with 7 samples.

How the data were processed

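Gene expression was measured in single cells of 7 mouse tumours by 3' end droplet sequencing (10x Chromium). The deposited files, 1 table per library, hold raw UMI counts per gene and cell barcode, whole numbers without normalization; per the submitters' processing notes they were made with Cell Ranger 2.0.2 and the mm10 genome build. Each file lists only genes seen in 3 or more of its barcodes (12376 to 18889 genes per file, 19415 over all files and 10719 in every file), and a gene not listed in a file was set to 0 there. The lowest barcode held 736 UMIs. Genes are named by symbol in the files. Coordinates are those of the GENCODE annotation of GRCm38, which is the assembly mm10 names; 123 of 125 named genes had an entry (BC048546 and Ctgf had none).

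Groups are the MYC and SHH subgroups of the labels, 5 libraries of 4 animals and 2 libraries of 2 animals. Animals, not cells, were the replicates, and 2 tumours whose titles share a number were taken as 1 animal and summed. MYC replicate 5 and SHH replicate 1 had a second sequencing run, per the labels. Barcodes were kept with 500 or more UMIs, 200 or more genes and at most 20% mitochondrial UMIs. Doublet scores were computed in each library of 200 or more cells with the Scrublet method of scanpy 1.11.5, and the highest-scoring 0.8% per 1000 cells were removed; 1861 of the 2039 cells removed were in MYC replicate 5. MYC replicate 3, with 183 cells, was not scored. Cells were clustered from log-normalised counts, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9) without batch correction, which gave 32 clusters.

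Clusters 3, 10, 13 and 18, which held genes of several cell types side by side, were split again, a choice made after seeing the data, for 65 clusters in all. A cluster was named from marker genes fixed before the data were examined when 3 or more markers were in at least 20% of its cells and at a log2 fold of at least 1, with 1 or more among its top 50 genes. Clusters with Ptprc in 20% or more of cells counted as haematopoietic. The rules that set unnamed, mixed and haematopoietic clusters apart were fixed after seeing the clusters. Tumour-candidate cells are those of clusters that carry no haematopoietic, vascular, mural, glial, ependymal, choroid or mature neuron name; the name does not rest on a genetic test of tumour origin. Clusters that mixed tumour and immune genes (750 cells) or macrophage and T cell genes (546 cells, 541 of them in MYC replicate 5) were left out of both classes. Cell names were rebuilt here, so they can differ from those of the study.

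UMI counts were summed per animal and class where the class had 20 or more cells, and tested with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F test) in R 4.3.3; p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The sums held 535873 to 66490868 UMIs for tumour-candidate cells and 154326 to 11246738 UMIs for macrophage/microglia-like cells, where the animal of MYC replicates 2 and 3 had 30 cells. Levels in these comparisons are TMM-normalised CPM, given as mean ± SD over animals, and the standard error of a log2 fold change is its size divided by the root of the F statistic. A gene at 0 UMIs in a group got a bound on its fold from 3 counts over the group, which leaves out UMIs hidden where a file does not list a gene seen in fewer than 3 barcodes. Named genes were the 10 largest and 10 smallest log2 fold changes among genes that passed, had a mean log2 CPM of 5 or more and did not overlap between groups. Pseudogene-type symbols, ribosomal protein genes, Xist and Y-linked genes were not taken for these ranks. Where fewer than 5 passed, the 10 smallest p-values were taken. Up to 4 leading members of each called list and a fixed set of genes of the tumour and of macrophages were added. In macrophages only 4 lower genes met the rule.

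The 28 gene lists fixed before the data were examined were tested with camera on limma-voom values (limma 3.58.1) at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry; lists with under 4 tested genes were left out. Shares of cells were compared by an exact permutation test over 15 splits of 6 animals, with Wilson 95% intervals for single shares. Ligand and receptor genes were compared between classes of the same animal on log2(CPM + 1), without TMM factors, by an exact sign-flip permutation test. In that design 20 changed genes of 60 in simulated data gave 0 calls, and 40 changed genes were all recovered with 1 false call.

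The tests were checked on simulated counts with 200 changed genes. In tumour-candidate cells edgeR recovered 1.5%, 56.7% and 84.8% of genes changed 4-, 16- and 64-fold among 11582 genes, with 3.1% false calls, and in macrophage/microglia-like cells 34.3%, 100% and 100% among 7459 genes, with 6% false calls. Over all cells it recovered 6%, 56.7% and 87.9% among 13311 genes with 2% false calls, and between trigeminal and basal tumours 0%, 52.2% and 92.4% among 9373 genes with 9.4% false calls. DESeq2 1.42.0, the alternative, gave 31.6% false calls in simulated tumour-candidate cells, 13% in macrophage/microglia-like cells, 38.7% over all cells and 26.7% between sites. A list moved by 2 on the log2 scale was called by camera in both classes with 0 other lists called, while with an estimated correlation its adjusted p was 0.056 in tumour-candidate and 0.0895 in macrophage/microglia-like cells. By fry its adjusted p was 0.045 and 0.042. The simulated genes varied independently of each other, so this check does not cover false calls of lists whose members move together. In the data the estimated correlation of interferon response genes was 0.668 in tumour-candidate and 0.684 in macrophage/microglia-like cells.

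RNA carried from another class was measured per animal as the median ratio of reference genes between the receiving and the source sums. Reference genes were macrophage/microglia and T cell markers for immune RNA, and mesenchymal, neural progenitor, neuronal, SHH signalling and onco-fetal list genes for tumour RNA. They had 100 CPM or more in the source sums, and genes under test were left out. This share times a gene's level in the source sums gave its predicted level, and carried RNA was taken not to account for a gene when its observed level was over 2 times the predicted one.

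Alternatives changed 1 choice at a time: the tool, normalization, low-count filter, libraries in place of animals, each animal left out, the sequencing runs as a covariate, a stricter cell filter, doublets kept, thinned depth, clustering at resolution 0.5, cells gated by marker UMIs, a minimum of 50 cells, removal of genes higher in the remaining cells, the denominator of shares and the pseudocount of the paired test. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9. Reads were not reprocessed.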

Results

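The series holds single-cell RNA sequencing of 7 atypical teratoid rhabdoid tumours, brain tumours of early life driven by loss of Smarcb1, a core subunit of the SWI/SNF chromatin remodelling complex. The tumours arose in Rosa26-CreERT2::Smarcb1 flox/flox mice, in which tamoxifen (50 mg/kg, given at day 6.5 post coitum) switches on a ubiquitous Cre recombinase that deletes Smarcb1. Viable cells (negative for the dead-cell dye 7-AAD) were sorted and captured in droplets with a 3' end chemistry that counts unique molecular identifiers (UMIs). The labels place 5 libraries in the MYC subgroup and 2 libraries in the SHH subgroup, here taken as 4 and 2 animals. MYC replicates 2 and 3 were a trigeminal nerve tumour and a lateral cerebellar tumour whose titles share a number, so they were taken as 1 animal and summed. MYC replicates 1 and 5 came from the basal cerebrum and MYC replicate 4 from the trigeminal nerve. Both SHH tumours lay in the striatum and subventricular zone, a site that no MYC tumour shared, so site and subgroup cannot be told apart between the groups. Animals were 12 to 27 weeks old in the MYC group and 14 and 16 weeks old in the SHH group.

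The files held 24433 barcodes, against 24199 cells stated in the series text, and 23938 barcodes passed the cell filter. After removal of 2039 putative doublets, 21899 cells were analysed. Depth was uneven: MYC replicate 5 alone held 111985990 UMIs and 62.5% of all barcodes, and the other 6 libraries held 2150925 to 9771059 UMIs. The median kept cell carried from 1728 UMIs in MYC replicate 4 to 9346 in MYC replicate 3. Intervals below cover counting error only.

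Smarcb1, the gene targeted in this model (chromosome 10, 75896769 to 75921617, minus strand, protein-coding, GRCm38), was low in tumour-candidate cells and present in the immune cells of the same tumours. Tumour-candidate cells held 2.26 (MYC replicate 1), 8.58 (MYC replicate 2), 2.60 (MYC replicate 3), 1.59 (MYC replicate 5), 10.2 (SHH replicate 1) and 1.18 (SHH replicate 2) Smarcb1 UMIs per 1000000 UMIs (CPM). In MYC replicate 4 there were 0 Smarcb1 UMIs among 535873, which allows up to 5.6 CPM. Macrophage/microglia-like cells of the same libraries held 18.9 to 59.2 CPM, where the lowest value rests on 1 UMI in 13 cells (MYC replicate 2) and the highest on 6 UMIs in 17 cells (MYC replicate 3). Smarcb1 was lower in tumour-candidate than in haematopoietic cells in 6 of 6 animals, by a mean log2(CPM + 1) difference of -3.75 ± 1.02 (SD, n = 6; exact two-sided sign-flip permutation p = 0.0312, the smallest that 6 animals allow). Smarca4, the ATPase of the same complex, chosen after its values were seen, was higher in tumour-candidate cells in 6 of 6 animals (0.89 ± 0.38 on the same scale, SD, n = 6; exact sign-flip permutation p = 0.0312). Tags come from the 3' end, and the sources used here do not say which exon is deleted, so these levels do not test the recombination itself.

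**Figure D1:**
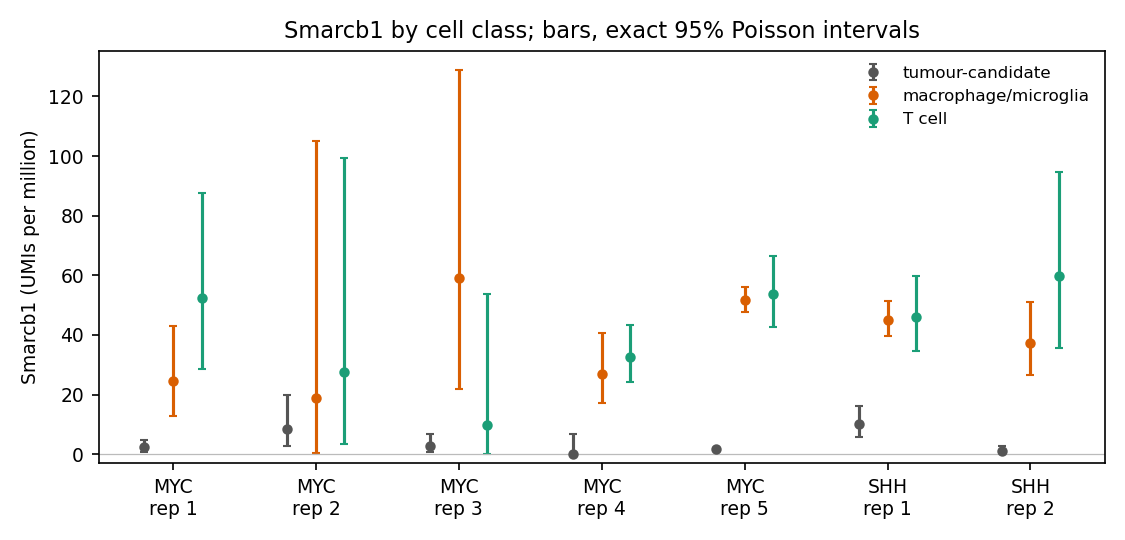
Smarcb1 level (vertical axis, CPM) in tumour-candidate, macrophage/microglia-like and T-cell-like cells of each library (horizontal axis); bars are exact 95% Poisson intervals. Tumour-candidate cells lie between 0 and 10.2 CPM, macrophage/microglia-like cells between 18.9 and 59.2 CPM and T-cell-like cells between 9.66 and 59.95 CPM. The lowest macrophage value (MYC replicate 2) and the lowest T cell value (MYC replicate 3) rest on 1 UMI each. In MYC replicate 2 the macrophage interval (0.48 to 105.1 CPM) and the T cell interval (3.34 to 99.51 CPM) overlap that of tumour-candidate cells (2.79 to 20.02 CPM). In MYC replicate 3 the T cell interval (0.24 to 53.81 CPM) overlaps that of tumour-candidate cells (0.71 to 6.67 CPM).

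The series concerns macrophages and tumour cells, and the first comparison asked how much of each tumour consisted of macrophages. Macrophage/microglia-like cells made up 16.6 ± 8.32% of analysed cells in MYC tumours (SD, n = 4 animals) and 35.3 ± 20.3% in SHH tumours (SD, n = 2). The single shares were 24.35% (Wilson 95% interval 20.1 to 29.1) in MYC replicate 1, 4.79% (3.38 to 6.76) in MYC replicates 2 and 3, 18.2% (16.6 to 19.8) in MYC replicate 4 and 19.0% (18.3 to 19.6) in MYC replicate 5. The SHH tumours held 49.6% (48.01 to 51.27) in replicate 1 and 20.95% (19.07 to 22.96) in replicate 2. The share lay below that of both SHH animals in 3 of 4 MYC animals. The difference of -18.7 percentage points did not pass (exact two-sided permutation p = 0.133, adjusted p = 0.567 over 17 classes), and the smallest p that 15 splits allow is 0.067. It was -4.38 points without SHH replicate 1, -33.07 points without SHH replicate 2 and -2.95 points when cells were gated by marker genes.

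T-cell-like cells averaged 17.0 ± 16.8% in MYC and 16.5 ± 9.56% in SHH tumours (SD, n = 4 and 2; exact permutation p = 1.0). Tumour-candidate cells averaged 37.7 ± 26.1% and 42.0 ± 35.2% (SD, n = 4 and 2; exact permutation p = 0.933), from 3.72% in MYC replicate 4 to 66.9% in SHH replicate 2. Neutrophil-like cells averaged 7.09 ± 12.3% in MYC animals (SD, n = 4). MYC replicate 2 held 158 of them among its 443 cells. In SHH animals 0 of 3622 and 0 of 1685 cells were given this name. By counting error alone these allow up to 0.083% and 0.178%. The absence depends on the clustering used. In the coarser alternative clustering the neutrophil-like cluster held 8 cells of SHH replicate 1 and 2 cells of SHH replicate 2. No class could pass an adjusted p of 0.05, since the smallest p that 15 splits allow is 0.067, so the test cannot show that shares were alike. Shares also carry the viability sort and the different depth of the libraries.

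**Figure D2:**
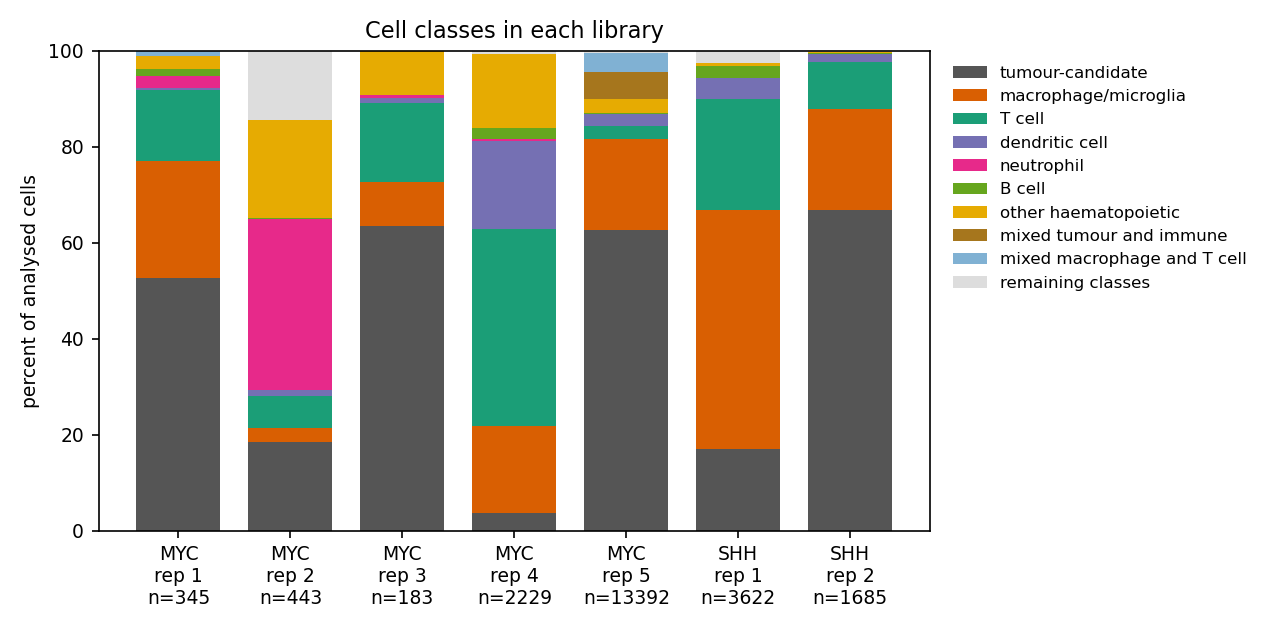
Share of analysed cells (vertical axis, percent) in each cell class for each library (horizontal axis, with the number of cells). Macrophage/microglia-like cells range from 2.93% in MYC replicate 2 to 49.6% in SHH replicate 1.

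In tumour-candidate cells, MYC and SHH tumours differed in 610 genes. Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874735, plus strand), stood at 998 ± 438 CPM in MYC and 0.43 ± 0.61 CPM in SHH tumours (SD, n = 4 and 2 animals; log2 fold change 10.79 ± 1.03 SE, edgeR adjusted p = 0.00787). Mycn, a MYC-family transcription factor (chromosome 12, 12936093 to 12941914, minus strand), stood at 172 ± 56.4 CPM in SHH and 0.52 ± 0.69 CPM in MYC tumours (log2 fold change -8.13 ± 0.77 SE, edgeR adjusted p = 0.0077). Of 11582 genes tested with edgeR's quasi-likelihood method, 610 passed a Benjamini-Hochberg adjusted p of 0.05, 300 higher and 310 lower in MYC tumours.

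Among the genes with the largest rises in MYC tumours, Msln (mesothelin, a surface glycoprotein) reached 747 ± 475 CPM and was at 0 UMIs in SHH tumours, at least 1630-fold higher when 3 counts over the SHH group are taken as the floor, or 470-fold without the deeper SHH replicate 2. On the same floor the homeobox gene Hoxc8 was at least 140.5-fold higher (40.5 without that animal), Ahnak2 at least 244-fold (70.5) and the mesodermal transcription factor Osr1 at least 118-fold (34.1). Col1a2, a chain of type I collagen, stood at 972 ± 457 CPM against 4.73 ± 4.56 CPM (log2 fold change 7.78 ± 1.04 SE). Plac8 stood at 1030 ± 592 against 4.90 ± 2.07 CPM, the actin-capping gene Capg at 585.5 ± 240.2 against 3.13 ± 3.82 CPM, Anxa1 at 767 ± 778 against 0.265 ± 0.375 CPM (1 UMI) and Tm4sf1 at 246 ± 202 against 0.53 ± 0.75 CPM (2 UMIs; SD, n = 4 and 2 throughout).

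Among the genes with the largest falls in MYC tumours, Hes5, a Notch target, was at 0 UMIs in MYC tumours and 100.6 ± 60.9 CPM in SHH tumours, at least 2129-fold lower, or 171-fold without the deep MYC replicate 5. Sox11, a transcription factor of immature neurons, stood at 1.65 ± 3.30 against 604 ± 280 CPM (log2 fold change -7.87 ± 1.41 SE). The Wnt antagonist Nkd1 stood at 0.18 ± 0.36 against 97.4 ± 4.38 CPM, and Mir124-2hg, the host transcript of a neuronal microRNA, at 0.068 ± 0.137 against 152 ± 11.2 CPM. Msx3, a homeobox gene of the dorsal neural tube, stood at 203 ± 202 CPM, Pantr1 at 193 ± 105, Alox15 at 102.4 ± 105.8, Ildr2 at 226 ± 58.6 and Lamp5 at 115 ± 149 CPM in SHH tumours. The MYC mean of each of these 5 was under 1 CPM. Smarcb1 itself stood at 2.14 ± 1.80 against 5.04 ± 5.61 CPM (edgeR adjusted p = 0.616).

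Myc, the transcription factor that names the MYC subgroup, stood at 40.4 ± 27.3 CPM in MYC and 3.40 ± 2.68 CPM in SHH tumours and did not pass the threshold (log2 fold change 3.70 ± 1.12 SE, edgeR adjusted p = 0.109). Neither did the hedgehog effector Gli2 (0.291 ± 0.582 against 10.3 ± 1.19 CPM, edgeR adjusted p = 0.0793), the hedgehog receptor Ptch1 (44.1 ± 21.5 against 144 ± 68.0 CPM, edgeR adjusted p = 0.099) or the methyltransferase Ezh2 (30.9 ± 12.4 against 88.5 ± 11.3 CPM, edgeR adjusted p = 0.0853). Cd274, Csf1, Spp1, Cd44, Cd47, Sirpa, Cxcl12, Cxcr4, Mif, Cd74 and Igf2 did not pass either.

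Groups did not overlap for 35.9% of tested genes, where chance gives 13.3%. Different clusters held the class in each group: clusters 9, 15, 22, 28, 29 and 31 came almost entirely from MYC replicate 5, and clusters 26 and 27 and the parts of cluster 18 almost entirely from SHH tumours. The count rests on both SHH animals: it was 14 without SHH replicate 1, 2 without SHH replicate 2, 269 without MYC replicate 5 and 1033 without MYC replicates 2 and 3. It was 319 with the number of sequencing runs as a covariate and 82 (14 higher, 68 lower) when cells were gated by marker genes, and DESeq2 called 1899 (1159 higher, 740 lower).

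**Figure D3:**
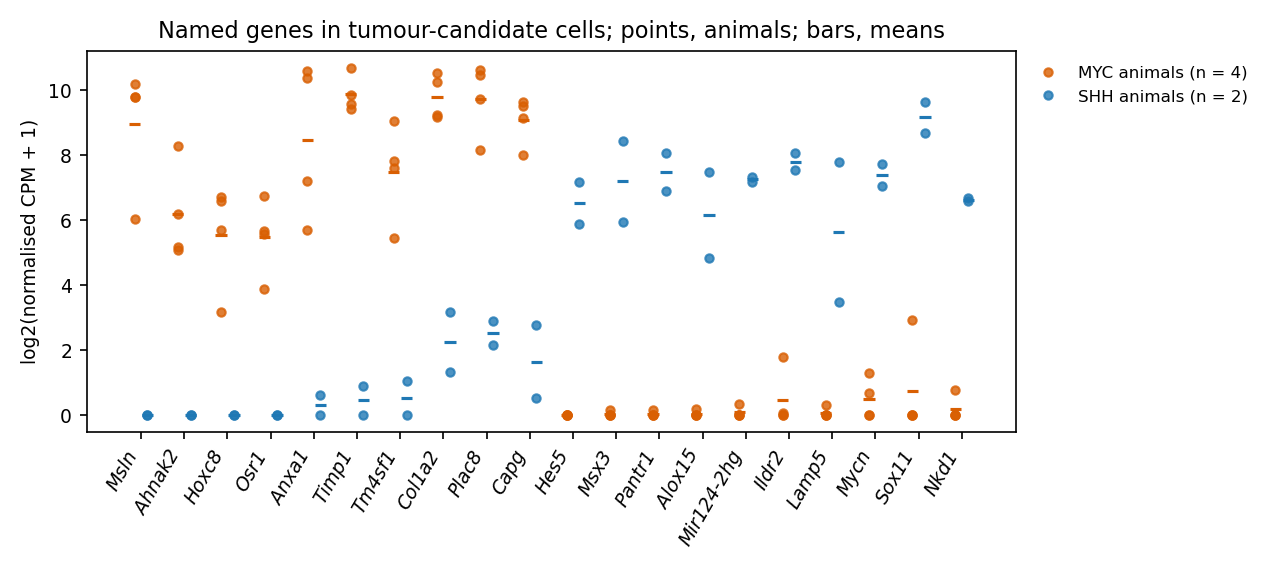
Levels of the 20 ranked genes in tumour-candidate cells (vertical axis, log2 of normalised CPM plus 1); points are animals and bars are group means. For each gene every animal of 1 group lies above every animal of the other.

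Of 25 gene lists tested in tumour-candidate cells, 12 were called by camera at its preset correlation of 0.01. None was called when the correlation was estimated, and fry called 11, 9 of them shared with camera. Fry did not call the mesenchymal and matrix (fry adjusted p = 0.0571), hypoxia and glycolysis (0.281) and inflammatory activation lists (0.275). It called the MYC family and PRC2 lists, which camera did not. Interferon response genes were higher in MYC tumours: 13 of 20 passed the test over all genes, 19 adjusted over the list alone, and none was lower (camera adjusted p = 8.2e-12; adjusted p = 0.306 with an estimated correlation). Ifit1, an antiviral RNA-binding protein (chromosome 19, 34640871 to 34650009, plus strand), stood at 432.5 ± 115.5 against 6.34 ± 2.28 CPM (log2 fold change 6.12 ± 0.52 SE). Bst2 (tetherin) stood at 1718 ± 698 against 27.1 ± 7.37 CPM, Oasl2 at 159 ± 103 against 1.60 ± 0.77 CPM and Xaf1 at 109 ± 42.6 against 1.97 ± 0.96 CPM. MHC class I genes were higher too, with 8 of 12 passing, 11 adjusted over the list alone (camera adjusted p = 2.06e-08; adjusted p = 0.306 with an estimated correlation). B2m, the invariant light chain of MHC class I, stood at 4704 ± 693 against 462 ± 230 CPM (log2 fold change 3.35 ± 0.43 SE). The peptide transporter Tap2 stood at 63.6 ± 21.0 against 6.82 ± 2.35 CPM, Tapbp at 250.5 ± 109.4 against 26.4 ± 0.62 CPM and H2-T23, which has close relatives that could share reads, at 71.7 ± 51.4 against 0.587 ± 0.081 CPM.

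Tumour-candidate cells include 3 clusters that the markers named fibroblast or meningeal (1286, 59 and 24 cells), all from MYC tumours, the largest with Smarcb1 at 1.78 CPM. In the class as a whole, mesenchymal and matrix genes were higher in MYC tumours, with 7 of 26 passing, 16 adjusted over the list alone, and none lower (camera adjusted p = 2.73e-05; adjusted p = 0.290 with an estimated correlation). Besides Timp1 and Col1a2, the collagen genes Col1a1 (190 ± 114 against 4.01 ± 1.92 CPM) and Col5a2 (254.5 ± 119.4 against 21.3 ± 7.59 CPM) passed. Hypoxia and glycolysis genes shifted as a list, with 0 of 18 passing and 6 adjusted over the list alone (camera adjusted p = 0.00231; adjusted p = 0.570 with an estimated correlation). Its leading member was hexokinase Hk2 at 49.5 ± 41.7 against 0.909 ± 0.537 CPM. Inflammatory activation genes shifted likewise, with 0 of 8 passing and 3 adjusted over the list alone (camera adjusted p = 0.036; adjusted p = 0.548 with an estimated correlation). Among its leading members was the chemokine gene Cxcl10, at 797 ± 852 against 5.61 ± 1.18 CPM.

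Lists of other cells and of tissue handling were also higher. Of 8 tested monocyte-derived macrophage genes, Plac8 and Ifitm6 were higher in MYC tumour-candidate cells, 5 adjusted over the list alone (camera adjusted p = 0.036; adjusted p = 0.290 with an estimated correlation). Dissociation stress genes were higher as well, with 4 of 17 passing (Hspa1b, Nr4a1, Ier3 and Atf3), 9 adjusted over the list alone (camera adjusted p = 2.73e-05; adjusted p = 0.124 with an estimated correlation). Immune marker genes stood in the tumour-candidate sums at 1.34% to 1.71% of their level in haematopoietic cells in MYC animals, and at 1.81% and 0.37% in the SHH animals.

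Lists of hedgehog, Notch and neural genes were lower in MYC tumours at the preset correlation. Of 14 SHH signalling genes, Mycn, the co-receptor Cdon (1.20 ± 1.37 against 45.5 ± 18.1 CPM) and the receptor Smo (23.4 ± 8.69 against 90.8 ± 1.83 CPM) were lower, 5 adjusted over the list alone (camera adjusted p = 2.48e-05; adjusted p = 0.113 with an estimated correlation). Of 14 Notch genes 4 were lower, among them Hes5, Dll1 and Hes6, and adjusted over the list alone 6 were lower and 1 higher (camera adjusted p = 0.0198; adjusted p = 0.374 with an estimated correlation). Tumour-candidate cells of SHH tumours include a cluster that the markers named neuroblast or neural progenitor (42 cells, 0 Smarcb1 UMIs). They also include an unnamed cluster with the astrocyte genes Slc1a2, Slc1a3 and Gfap among its leading genes (69 cells, Smarcb1 at 19.2 CPM from 3 UMIs). In the class as a whole, of 11 neural progenitor genes 5 were lower, 7 adjusted over the list alone (camera adjusted p = 2.73e-05; adjusted p = 0.113 with an estimated correlation). They include the radial glia fatty acid-binding protein Fabp7 (15.6 ± 14.6 against 2624 ± 987 CPM) and Msi1 (1.91 ± 2.36 against 74.1 ± 3.63 CPM). Of 13 neuronal differentiation genes 3 were lower, 4 adjusted over the list alone (camera adjusted p = 0.0352; adjusted p = 0.429 with an estimated correlation). These were Elavl4 (0.116 ± 0.231 against 51.7 ± 9.33 CPM), Map2 (2.48 ± 1.39 against 62.0 ± 57.0 CPM) and Sox11. SWI/SNF subunits shifted lower as a list with 0 of 19 passing and 0 adjusted over the list alone (camera adjusted p = 0.036; adjusted p = 0.290 with an estimated correlation), led by Smarcd3 at 15.8 ± 10.8 against 85.7 ± 45.5 CPM.

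The other 13 lists were not called by camera in tumour-candidate cells at the preset correlation. MYC targets (0 of 40 genes passing, camera adjusted p = 0.369) and proliferation genes (0 of 20, camera adjusted p = 0.958) were among them, both also at 0 adjusted over the list alone. HOX genes had 2 members higher (Hoxc8 and Hoxc6, camera adjusted p = 0.783), also 2 adjusted over the list alone. The MYC family had 2 lower (camera adjusted p = 0.427), and 2 lower and 1 higher adjusted over the list alone. Fry called this list lower in MYC tumours (fry adjusted p = 0.00625). Onco-fetal genes had 3 higher and 1 lower (camera adjusted p = 0.958), and 3 higher and 4 lower adjusted over the list alone. Camera adjusted p was 0.427 for PRC2, 0.216 for drug efflux and detoxification, 0.369 for MHC class II and 0.0723 for homeostatic microglia. It was 0.176 for lipid and damage associated genes, 0.691 for complement, 0.843 for haemoglobin and 0.691 for mitochondrial transcripts. Drug efflux had 1 gene higher (2 adjusted over the list alone), mitochondrial transcripts 1 higher (also 1), and lipid and damage associated genes 1 higher and 1 lower (5 and 1 adjusted over the list alone). PRC2 had 0 passing and 3 lower adjusted over the list alone, and fry called it lower in MYC tumours (fry adjusted p = 0.0373). The other 4 lists had 0 by both adjustments. The median and the mean or the test differed in sign for onco-fetal, complement and haemoglobin genes. Melanosomal, alternative activation and T cell exhaustion lists had under 4 tested genes and were not tested.

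The labels also give the site of each MYC tumour. Tumour-candidate cells of 2 trigeminal nerve tumours (MYC replicates 2 and 4) were compared with those of 2 basal cerebrum tumours (MYC replicates 1 and 5). The sums held 82 and 83 cells of MYC replicates 2 and 4, and 182 and 8388 cells of MYC replicates 1 and 5. No gene passed at an adjusted p of 0.05 among 9373 tested with edgeR, 743 had an unadjusted p under 0.05, and DESeq2 called 167. Among genes with a mean log2 CPM of 5 or more, the 10 with the smallest p-values all had an edgeR adjusted p of 0.522. Among them the homeobox gene Hoxa5 (chromosome 6, 52201754 to 52204587, minus strand) stood at 74.8 ± 18.2 CPM in trigeminal and 0.17 ± 0.24 CPM in basal tumours (SD, n = 2 and 2). The matrix gene Fbln5 stood at 151 ± 3.59 against 16.3 ± 0.95 CPM, Gprc5b at 127 ± 41.1 against 6.38 ± 3.34 CPM and the sulfatase Sulf1 at 123 ± 45.9 against 14.5 ± 1.22 CPM. In the other direction the epithelial gene Sfn stood at 4.60 ± 4.12 against 811 ± 112 CPM, the enkephalin precursor gene Penk at 0.94 ± 1.33 against 555 ± 388 CPM, Spint2 at 32.3 ± 7.48 against 409 ± 178 CPM and Ctgf at 1.69 ± 2.38 against 125 ± 14.1 CPM. BC048546 and the neurotensin gene Nts were at 0 UMIs in trigeminal tumours and at 195 ± 2.69 and 99.1 ± 13.8 CPM in basal tumours. With every gene of 1 or more UMIs tested, edgeR called 755. Groups did not overlap for 39.5% of genes, where chance gives 33.3%. In the clustering at resolution 0.5, 80 cells of MYC replicate 2 fell in a cluster that the markers named fibroblast or meningeal. That cluster held 32.05 CPM of Smarcb1, with Rgs5, Acta2 and Cldn5 among its leading genes, and included 42 cells of MYC replicate 5. The tumour-candidate cells of MYC replicate 2 held 8.58 CPM of Smarcb1. Whether fibroblast or meningeal cells account for the genes higher in trigeminal tumours was not tested.

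Over all cells together, MYC and SHH tumours differed in 1 of 13311 genes by edgeR. Hes5, named after its values were seen, stood at 0.0058 ± 0.0116 CPM in MYC and 36.9 ± 5.07 CPM in SHH tumours (2 against 572 UMIs, SD, n = 4 and 2, edgeR adjusted p = 0.00944). No other gene passed; the values that follow are of the 10 named genes with the smallest p among those with a mean log2 CPM of 5 or more, which did not pass. They include the calcium-binding S100a11 (1409 ± 364 against 102.4 ± 21.5 CPM, edgeR adjusted p = 0.0795) and S100a6 (5351 ± 2072 against 260.4 ± 40.3 CPM, edgeR adjusted p = 0.0795), higher on average in MYC tumours. The interferon-induced Ifitm2 stood at 1267 ± 357 against 98.4 ± 38.4 CPM and the galectin Lgals1 at 2555 ± 764 against 310.2 ± 88.0 CPM. In SHH tumours the means were higher for the choroid plexus transport protein Ttr (0.044 ± 0.087 against 1143 ± 1533 CPM), Msx3 (0.0233 ± 0.0465 against 128 ± 160 CPM), Ildr2 (0.266 ± 0.457 against 96.0 ± 47.0 CPM), Fez1 (2.72 ± 2.54 against 326 ± 231 CPM), Kif21a (6.11 ± 2.91 against 129 ± 48.6 CPM) and Slc22a17 (8.55 ± 4.76 against 178 ± 101 CPM). These sums mix cell classes whose shares vary between animals; 1547 genes had an unadjusted p under 0.05 and DESeq2 called 786. The count was 0 without MYC replicate 1, MYC replicate 5, SHH replicate 1 or SHH replicate 2, and 2 without MYC replicates 2 and 3. After thinning to equal UMIs 2 genes were called, and Hes5 was not among them.

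Macrophage/microglia-like cells of MYC and SHH tumours differed in 45 of 7459 genes by edgeR, 31 higher and 14 lower in MYC tumours. Tgfbi, a secreted matrix protein made by monocyte-derived macrophages (chromosome 13, 56609523 to 56639562, plus strand), stood at 1296 ± 327 CPM in MYC and 173 ± 0.37 CPM in SHH tumours (SD, n = 4 and 2; log2 fold change 2.90 ± 0.45 SE, edgeR adjusted p = 0.0274). Calcium-binding S100 genes were among them: S100a4 stood at 507 ± 378 against 2.27 ± 3.22 CPM, S100a10 at 542 ± 410 against 11.2 ± 11.4 CPM and S100a11 at 710 ± 595 against 24.2 ± 2.69 CPM. S100a6 stood at 1532 ± 764 against 31.6 ± 21.1 CPM, but it was also abundant in tumour-candidate cells of MYC animals (9833 CPM before normalization), and in 1 of these 4 animals its macrophage level was only 1.96 times what carried tumour RNA predicts. Before normalization S100a10 and S100a11 were also higher in MYC tumour-candidate cells (1156 and 1354 CPM) than in MYC macrophages (554 and 717 CPM). Their macrophage levels were 3.17 and 3.13 times the predicted ones in the lowest MYC animal. T-cell-like cells of MYC animals held 1528 and 826 CPM of these 2 genes, and RNA carried from T cells was not tested. The lectin gene Clec4a1 stood at 203 ± 35.5 against 2.58 ± 3.65 CPM, Ifitm1 at 207 ± 143 against 2.18 ± 0.13 CPM, Sirpb1c, one of a family of close paralogs, at 213.5 ± 153.2 against 6.24 ± 0.05 CPM and Ahnak at 143 ± 77.9 against 3.21 ± 3.06 CPM. Trem1, an amplifying receptor of myeloid inflammation, stood at 59.9 ± 61.9 against 0.207 ± 0.292 CPM (2 UMIs), and Slfn4 at 91.8 ± 90.6 CPM against 0 UMIs, at least 177-fold higher, or 29.3-fold without the deeper SHH replicate 1.

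Lower in MYC macrophages were the extracellular protease gene Klk8 (3.26 ± 2.41 against 83.6 ± 96.1 CPM), Plxdc2 (19.2 ± 14.5 against 180.5 ± 46.8 CPM), the sulfotransferase Chst1 (7.31 ± 4.09 against 73.5 ± 13.8 CPM) and Fabp7 (3.40 ± 2.99 against 171 ± 48.4 CPM). Before normalization Klk8 was higher in T-cell-like cells (103.9 CPM in MYC and 167.7 CPM in SHH animals) than in macrophages (3.39 and 75.91 CPM). RNA carried from T cells was not tested. Fabp7 was far higher in the tumour-candidate cells of the same SHH tumours (2909 CPM before normalization), and its macrophage level was 0.74 and 1.73 times what carried tumour RNA predicts in the SHH animals. In the class, Cd44 stood at 178 ± 130 against 10.8 ± 0.97 CPM (edgeR adjusted p = 0.067), and Smarcb1, Myc, Ezh2, Csf1, Spp1, Cd47, Sirpa, Cxcr4, Mif and Cd74 did not pass either. Clusters 0, 4 and 7 held most MYC cells of the class and clusters 17 and 20 most SHH cells. The count was 4 without SHH replicate 1, 3 without SHH replicate 2, 169 without MYC replicate 5, 84 without MYC replicates 2 and 3, 78 without MYC replicate 1 and 36 without MYC replicate 4 (27 shared). It was 11 with the number of sequencing runs as a covariate (10 shared), 7 after thinning to equal UMIs (all shared) and 5 with gated cells (1 shared), and DESeq2 called 370.

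**Figure D4:**
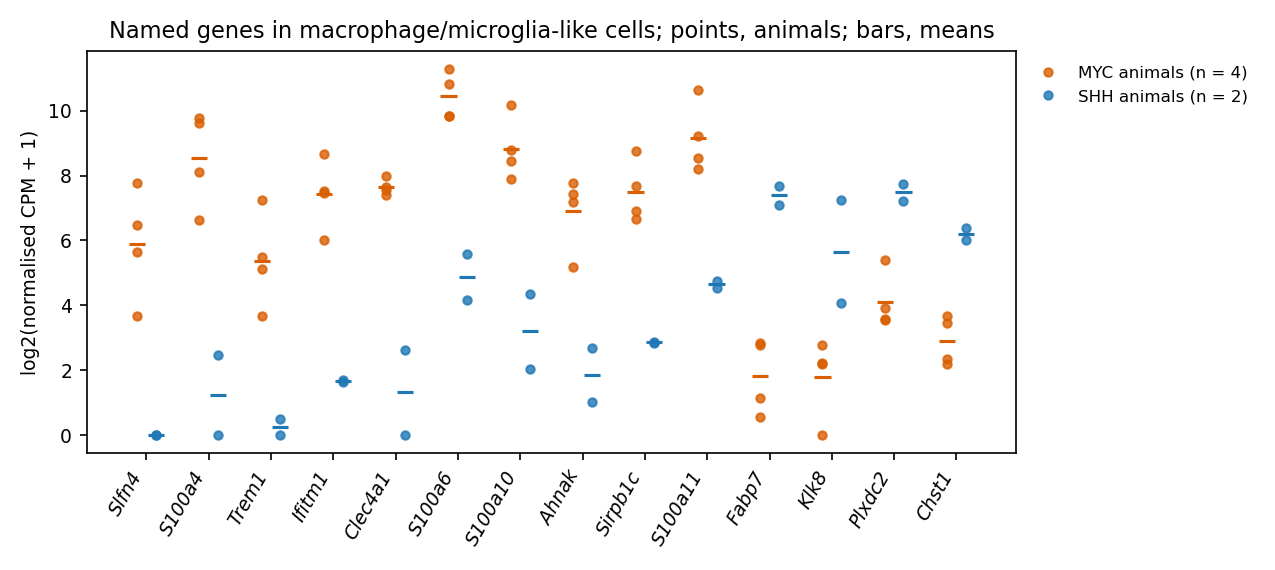
Levels of the 14 ranked genes in macrophage/microglia-like cells (vertical axis, log2 of normalised CPM plus 1); points are animals and bars are group means. Every MYC animal lies above both SHH animals for the 10 genes on the left and below them for the 4 on the right.

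Of 22 gene lists tested in macrophage/microglia-like cells, 6 were called by camera at the preset correlation, and none with an estimated correlation or by fry. Monocyte-derived macrophage genes were higher in MYC tumours, with Tgfbi passing among 15, and 11 adjusted over the list alone (camera adjusted p = 0.000103; adjusted p = 0.524 with an estimated correlation). Ly6c2, a marker of inflammatory monocytes, stood at 415 ± 415 against 6.52 ± 7.74 CPM, Gda at 109 ± 87.5 against 1.34 ± 1.90 CPM and Emilin2 at 96.5 ± 62.4 against 6.12 ± 2.74 CPM. Homeostatic microglia genes shifted lower in MYC tumours, with 0 of 14 passing and 1 adjusted over the list alone (camera adjusted p = 1.24e-10; adjusted p = 0.4625 with an estimated correlation). Olfml3 stood at 38.9 ± 30.8 against 342 ± 231 CPM and Siglech at 27.1 ± 48.1 against 280 ± 135 CPM.

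Interferon response genes shifted higher, with 0 of 20 passing and 6 adjusted over the list alone (camera adjusted p = 1.27e-06; adjusted p = 0.617 with an estimated correlation); Isg15 stood at 1285 ± 1025 against 168 ± 14.4 CPM. Hypoxia and glycolysis genes did so with 0 of 17 passing and 4 adjusted over the list alone (camera adjusted p = 0.0151; adjusted p = 0.836 with an estimated correlation), led by Pfkp at 71.9 ± 80.4 against 2.60 ± 0.71 CPM. Lipid and damage associated genes shifted lower, with 0 of 16 passing, and adjusted over the list alone 9 were lower and 3 higher (camera adjusted p = 0.0111; adjusted p = 0.4625 with an estimated correlation). The lysosomal protease gene Ctsd stood at 1377 ± 1126 against 8119 ± 894 CPM and Cst7 at 38.2 ± 26.1 against 379 ± 284 CPM, while Gpnmb stood higher at 28.6 ± 26.8 against 2.81 ± 0.46 CPM. The T cell exhaustion list had 4 tested genes, 0 passing and 2 lower adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.4625 with an estimated correlation). Its leading members here were the checkpoint receptor genes Pdcd1 (6.13 ± 6.32 against 60.3 ± 20.2 CPM) and Lag3 (53.5 ± 73.3 against 317 ± 225 CPM).

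The other 16 lists tested in this class had camera adjusted p from 0.0918 (drug efflux and detoxification) to 0.959 (SWI/SNF subunits and onco-fetal genes). MHC class I (0.609), MHC class II (0.387), complement (0.648), alternative activation (0.387), inflammatory activation (0.387) and proliferation (0.218) lay between. So did Notch signalling (0.387), MYC targets (0.958), MYC family (0.387), mesenchymal and matrix (0.113), PRC2 (0.344), dissociation stress (0.614) and mitochondrial transcripts (0.181). A gene passed in the mesenchymal list (6 higher and 2 lower adjusted over the list alone) and in complement (2 higher adjusted over the list alone), and 0 in the other 14 lists. Adjusted over the list alone, 4 of these had genes that passed, all higher: alternative activation (4), Notch signalling (2), MYC family (1) and PRC2 (1). The median and the mean differed in sign for MYC targets. SHH signalling, neural progenitor, neuronal differentiation, HOX, melanosomal and haemoglobin lists had under 4 tested genes.

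The last comparison set 30 ligand and 30 receptor genes side by side in macrophage/microglia-like and tumour-candidate cells of the same animals. In all 6 animals 22 genes stood higher in macrophages (12 receptors and 10 ligands) and 13 higher in tumour-candidate cells (9 ligands and 4 receptors). The genes named here were chosen after their values were seen, apart from Csf1, Sirpa, Igf2 and Cxcl12. On the macrophage side were the lipid receptor Trem2 (772 ± 610.5 against 8.43 ± 16.7 CPM, SD, n = 6), the inhibitory receptor Sirpa (178.5 ± 91.0 against 21.7 ± 23.4 CPM) and the kinase Axl (220 ± 88.8 against 50.3 ± 61.5 CPM). The cytokine genes Il1b (665 ± 660 against 7.99 ± 10.8 CPM), Osm (174 ± 195 against 1.94 ± 1.72 CPM) and Tgfb1 (195.5 ± 167.3 against 15.9 ± 16.4 CPM) stood there too. Csf1r and Cx3cr1, also in this set, helped to name the class. On the tumour side were the growth factor genes Ptn (10.7 ± 14.7 in macrophages against 502 ± 562 CPM), Mdk (6.53 ± 5.99 against 287 ± 226 CPM) and Igf2 (0.738 ± 0.808 against 161 ± 218 CPM). The chemokine genes Cx3cl1 (1.88 ± 2.60 against 43.4 ± 23.9 CPM) and Cxcl12 (0.369 ± 0.505 against 29.3 ± 51.8 CPM) followed, with Cd200, Cd24a, Tgfb2, Hbegf and the receptors Igf1r, Igf2r, Egfr and Pdgfra. Each of these 35 genes had the smallest p that 6 animals allow (exact two-sided sign-flip permutation p = 0.0312), and none passed after adjustment over 60 genes (adjusted p = 0.0536). Csf1, the growth factor of macrophages, stood at 15.9 ± 22.1 against 42.3 ± 50.3 CPM, higher in tumour-candidate cells in 5 of 6 animals (exact sign-flip permutation p = 0.0938, adjusted p = 0.128).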

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

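Values in this part lay far from the other MYC animals or libraries, moved in opposite directions in the 2 groups, or came from barcodes outside the comparisons. The tests on promyelocyte genes were chosen after the result was seen. Of 169 sets of MYC values examined, 34 held such a value, where chance gives about 1 in 20 (8.4) in independent sets of normally spread values. Many of these sets are linked, since they come from the same animals. Where all other values of a set were 0, any value above 0 was flagged whatever its size. The 34 therefore cannot be read as an excess over 8.4.

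MYC replicate 5 stood apart by depth, with 15282 barcodes and 111985990 UMIs against 214 to 2271 barcodes and 2150925 to 5334711 UMIs in the other MYC libraries. Astrocyte-like (0.06%), endothelial-like (0.18%) and mural-like cells (0.04%) and clusters mixing tumour and immune genes (5.6%) were seen in it and not in the other 3 MYC animals, where 0 cells allow up to 0.87%, 0.479% and 0.135%. Only the mixed clusters exceed all of these limits. In the clustering at resolution 0.5, clusters mixing tumour and immune genes had doublet calls for 77.8%, 76.8% and 13.8% of their cells. The doublet rate assumed from cell number was 12.2% in MYC replicate 5 and at most 1.81% in the other MYC libraries. Remaining doublets thus stay open as the source of the mixed clusters. Some genes were seen at low levels in it and at 0 UMIs in the other 3 MYC animals: over all cells Msx3 (0.093 CPM), Ttr (0.174 CPM) and Gli2 (0.85 CPM), and in tumour-candidate cells Msx3 (0.103 CPM), Pantr1 (0.103 CPM), Alox15 (0.137 CPM), Mir124-2hg (0.274 CPM), Lamp5 (0.24 CPM), Sox11 (6.59 CPM), Nkd1 (0.719 CPM), Gli2 (1.16 CPM), Dll1 (0.50 CPM) and Elavl4 (0.462 CPM). At the depth of the others 0 UMIs allow 0.568 to 0.787 CPM over all cells and 1.19 to 5.82 CPM in tumour-candidate cells. Only Gli2 over all cells and Sox11 exceed these limits in every animal, so the other contrasts can follow from depth alone. Both exceed the highest limit narrowly (0.85 against 0.787 CPM and 6.59 against 5.82 CPM). A gene seen in fewer than 3 barcodes of a library is not listed there, so a 0 can hide a few UMIs and depth stays open for these 2 as well. Msln was lower in its tumour-candidate cells (64.2 CPM against 876.5 to 1166 CPM), and Igf2 over all its cells was 0.94 CPM against 62.2 to 110.8 CPM.

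In MYC replicate 4, dendritic-like cells made up 18.35% of cells against 0.29% to 2.52%, Kif21a over all cells was 1.85 CPM against 7.01 to 8.40 CPM, and Actl6a in tumour-candidate cells was 29.1 CPM against 52.6 to 58.5 CPM. Cst7 was at 0 CPM in the macrophage/microglia-like cells of MYC replicate 1 against 44.3 to 58.3 CPM. In the animal of MYC replicates 2 and 3, Xist stood at 1081 CPM over all cells and 1684 CPM in tumour-candidate cells, Ildr2 at 0.947 CPM and 2.4 CPM, Bst2 in tumour-candidate cells at 699 CPM against 1861 to 2253 CPM, and Nr4a1 at 33.1 CPM against 82.2 to 94.97 CPM.

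Among 60 ligand and receptor genes, those that went opposite ways in the 2 groups were picked out for it, so no test of the gap is given. Pros1 stood lower in macrophages than in tumour-candidate cells in every MYC animal and higher in both SHH animals (mean log2 differences -1.40 and 1.60, a gap of -3.0). Cxcr4 moved the opposite way (3.42 in MYC and -0.91 in SHH animals, a gap of 4.33).

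Granulocyte and erythroid cells made up much of MYC replicate 2. In its animal neutrophil-like cells were 25.4%, erythroid-like cells 5.27% and mast cell or basophil-like cells 4.95% of cells, and 201 of the 637 barcodes of MYC replicate 2 were over 50% haemoglobin, against 7 in MYC replicate 1 and 15 in MYC replicate 3. Mature blood as the only source was argued against, since 27.31% of the analysed cells of MYC replicate 2 held UMIs of 3 or more of the promyelocyte genes Mpo, Elane, Prtn3, Ctsg and Ms4a3, known from immature granulocytes, at a share above any of its 124 tumour-candidate, macrophage/microglia-like and T-cell-like cells (at most 0.0718% of UMIs). They were 70 of 90 other haematopoietic, 41 of 158 neutrophil-like, 10 of 31 mast cell or basophil-like and 0 of 33 erythroid-like cells. Mature blood thus stays open for the erythroid-like and most neutrophil-like cells, and was not tested for the haemoglobin barcodes. That cells with promyelocyte genes occur in trigeminal tumours in general was argued against too, since 0 of 2229 cells (0%) of the other trigeminal library held 3 or more of these genes. Marrow of neighbouring bone taken with this tumour stays open and was not tested, as does blood formation within the tumour.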

How the results depend on the processing

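The alternatives with MYC replicate 2 left out of its animal's sum and with tumour-candidate clusters of Smarcb1 under 20 CPM were chosen after seeing the data; the others were set before. No named gene or list changed direction while called. Genes called over all cells (1) numbered 786 with DESeq2, 5 without the count filter, 39 with libraries as samples, 2 with sequencing runs as a covariate, 2 when thinned (0 shared), 4 without MYC replicate 2 and 0 to 2 with each animal left out. In tumour-candidate cells (610) there were 1899 with DESeq2 (605 shared), 319 with the covariate (295 shared), 82 with gated cells (77 shared) and 2 to 1033 with each animal left out, and 472 to 687 under the other settings. In macrophage/microglia-like cells (45) there were 370 with DESeq2 and 335 without the count filter (45 shared in each), 32 with RLE size factors (7 of 15 named genes lost their call), 11 with the covariate (10 shared), 7 when thinned (all shared) and 5 with gated cells (1 shared), where 14 of 15 named genes lost their call. There were 84 with libraries as samples, with at least 50 cells or without MYC replicate 2, which give the same sums, and 3 to 169 with each animal left out (36 without MYC replicate 4, 27 shared, where 9 of 15 named genes lost their call). Without genes higher in the remaining cells of the tumour, 12 were called, all among the 13 called genes still tested, so the lower count follows from fewer genes. Between sites (0) there were 167 with DESeq2 and 755 without the count filter. In both classes 0 lists were called with an estimated correlation (from 12 and 6); fry called 11 and 0; with each animal left out, 10 to 14 and 5 to 10 were called. Where an animal was left out and 1 SHH animal remained, it is assumed to vary like the MYC animals. Otherwise the cause was not tested. Without the count filter the median log2 fold change of all genes moved to 0.304 (tumour-candidate), 0.21 (all cells) and -0.557 (between sites).

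The share difference stayed negative under all alternatives (-33.07 to -2.95 points, and -0.16 as a ratio to tumour-candidate cells). No ligand or receptor gene passed with another pseudocount or gated cells; with libraries as samples or an animal left out none could, since the smallest p of 5 samples is 0.0625. Of 892 values of named macrophage genes 727 stayed on their side of the threshold, 101 lost and 64 gained a call; of 1343 in tumour-candidate cells 1144 stayed, 166 lost and 33 gained one. Uncalled values changed sign in 20 and 10 cases. No paired analysis was possible because replicate numbers follow accession order and the groups hold different animals. On simulated data 4-fold changes were recovered at 1.5% in tumour-candidate cells, and 83 tumour-candidate cells of MYC replicate 4 and 30 macrophages of MYC replicates 2 and 3 gave the lowest depths.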

Other observations

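Of the tests in this part, those of tumour site, of tumour RNA in macrophages and of kinds of macrophage were chosen after the result was seen; that of immune RNA in tumour-candidate cells was not. Lymphoid and dendritic cells of these tumours fell into clusters with distinct leading genes. The largest T-cell-like cluster (1416 cells, 700 of MYC and 716 of SHH tumours) was led by genes of cytotoxic lymphocytes, among them Nkg7, Gzma, Gzmk, Ccl5 and Cd8a. Another (568 cells, 386 of MYC tumours) was led by Tnfrsf4, Ctla4, Ikzf2 and Foxp3, genes known from regulatory T cells, and another (403 cells, 295 of MYC tumours) by Il17a, Il22 and Cxcr6. Dendritic-like cells formed a cluster led by Xcr1 and Clec9a (555 cells) and another led by Ccr7, Ccl22 and Fscn1 (385 cells), genes of migrating dendritic cells. Shares of these clusters were not compared between groups.

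Some unnamed haematopoietic clusters came mostly from 1 library. Of 240 cells led by Siglech, Ccr9 and Cox6a2, genes known from plasmacytoid dendritic cells, 181 were from MYC replicate 4, and of 164 cells led by Il1rl1, Gata3 and Calca 161 were. Of 373 cells led by Cd207 and H2-M2, 358 were from MYC replicate 5. A group of 17 cells, 16 of them from MYC replicate 3, was led by the osteoclast genes Ctsk, Acp5, Mmp9, Ocstamp and Dcstamp. Xist stood at 770 CPM in MYC replicate 2 and 1462 CPM in MYC replicate 3, with 0 UMIs of Y-linked genes in either. The other 5 libraries held at most 3.14 CPM of Xist and 116 to 196 CPM of Y-linked genes. The 2 tumours taken as 1 animal thus match each other in these genes and differ from the rest, which does not by itself show that they came from 1 animal.

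In MYC tumour-candidate cells 13 of 20 interferon response and 8 of 12 MHC class I genes were higher, while neither list was called with an estimated correlation (camera adjusted p = 0.306 for each). RNA or doublets of immune cells that carry the marker genes were argued against as the source of these levels. The median of the observed level over that predicted from immune marker genes in the same sums was 48.9 or more in every MYC animal over the 21 called genes. The same markers helped to keep immune clusters out of the class, so immune cells without them are not covered. The median was also above the bound of 2 in the SHH animals (3.98 and 12.0), so passing it does not by itself mark MYC tumours. The site of the tumour cannot be told apart from the subgroup, since 0 sites were shared by both groups. Age, tissue handling and the animals themselves stay open. A biological difference of the MYC subgroup stays open too and was not tested apart from site.

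Genes that differed in macrophage/microglia-like cells could come from free RNA of tumour cells. Over all 31 genes higher in MYC animals the median of observed over predicted level was 81.11 or more in every MYC animal, and over all 14 lower ones it was 15.4 or more in both SHH animals, which argued against this for the genes as a whole. It was not argued against for some of them: S100a6 and Timp1 were at 1.96 and 0.87 in their lowest MYC animal, and Fabp7, Fez1, Ly6h, Sox11 and Sox4 lay between 0.41 and 1.73 in both SHH animals. Ifitm1, at 2.13 in its lowest animal, was close to the bound of 2. Different kinds of macrophage in place of a change within a kind cannot be told apart from it, since 0 clusters of the class held 20 or more cells in 2 or more animals of each group.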
